A study of Arabidopsis thaliana with 12 samples.

How the data were processed

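RNA from shoots and roots of 8-day-old Arabidopsis thaliana seedlings was sequenced in wild-type Col-0 (WT) and in plants that overexpress CCA1 (CCA1-ox), with 3 libraries in each of the 4 groups and 12 libraries in all. Per the labels' protocols, total RNA was isolated on columns with DNase digestion and made into libraries with a stranded kit. The labels do not give the time of day of harvest, so a fold change of a clock gene may reflect its phase in WT as well as its level. The labels name no separate cultures, so the p-values given here measure only the spread between these samples, which may be technical.

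The values are the FPKM (fragments per kilobase of gene, scaled to library size) that the authors deposited for 33010 genes, with gene positions on TAIR10 per the submitters' processing notes. The aligner, the counter and the setting for strand are not given in the sources used here. Of the 20975 genes tested, 1161 overlap another gene on the same strand and 5974 overlap one on the other strand; values of such genes, and of near-identical paralogs, are uncertain because a fragment may belong to either copy. Multiplying the deposited FPKM by gene length gave whole multiples of 1 step in each library: 100% of values were whole within 0.1, so the fragments behind each value were recovered. Summed over genes these were 39683894 to 44242304 in WT shoots, 37216665 to 39814773 in CCA1-ox shoots, 37773138 to 45051329 in WT roots and 27142671 to 38537638 in CCA1-ox roots. The library size in the deposited FPKM was not this sum: size used over sum averaged 0.906 ± 0.00193 (SD, n = 3) in WT shoots, 0.976 ± 0.00163 in CCA1-ox shoots, 1.15 ± 0.00460 in WT roots and 1.10 ± 0.00376 in CCA1-ox roots. The 10 most abundant genes held 7.22%, 6.36%, 4.07% and 4.35% of fragments in these groups.

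Replicates were compared before averaging. No library column was identical to another, and in the 12 replicate pairs the median chi-square over genes was 1.01 to 1.29, against 0.455 for sampling noise alone, so no pair looked like 1 library deposited again. For genes with at least 500 fragments the median coefficient of variation within a group was 3.14% to 3.67%. Counting alone would give a median of 2.49% to 2.67%. Such coefficients do not add. The spread beyond counting, from a trimmed mean of the excess variance over genes, was 2.85% to 3.34%.

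Genes with an FPKM of at least 1 in at least 3 libraries were tested, 20975 in all; 5439 of the other 12035 had no value above 0. A linear model of the 4 group means was fitted to log2(FPKM + 1) in all 12 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow a mean-variance trend (8 residual degrees of freedom). Contrasts were CCA1-ox against WT in shoots, the same in roots, the root effect minus the shoot effect (the interaction), and WT roots against WT shoots. A higher or lower effect in roots means the sign of this difference, not a larger or smaller change. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. On simulated data with 50 genes changed at each size among the 20975, the shoot comparison recovered 25, 37, 45 and 50 genes at log2 changes of 0.25, 0.5, 1 and 2 and called 10 of 20775 unchanged genes. For roots it recovered 20, 36, 49 and 48 and called 6. Far fewer genes were changed in the simulation than were called in the data, 11637 in shoots and 7612 in roots. The cutoff under Benjamini-Hochberg adjustment depends on that share, so these counts do not give the recovery or the false calls in the data.

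Before the data were examined, 30 gene lists with 442 genes were fixed from general knowledge, of which 403 genes were tested. Lists were tested with limma's camera at a preset correlation of 0.01 against all other genes, with adjustment over the 30 lists. The lists cover morning and evening clock genes, plasma membrane H+-ATPases, clade D PP2C phosphatases, SAUR genes, vacuolar proton pumps, cation/H+ exchangers, nutrient and sugar uptake, iron deficiency, phosphate starvation, auxin transport, auxin synthesis and response, expansins, xyloglucan endotransglucosylases, light signalling, flowering, light harvesting with the Rubisco small subunit, starch, flavonoids, glucosinolates, cold and dehydration, heat shock, defence, aquaporins, cell division, and markers of root hairs, root cap, endodermis, xylem and guard cells.

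Named genes follow a rule fixed at the same time. It takes CCA1, all measured H+-ATPases (AHA) and, per list and tissue, up to 4 called members with the largest change, or the most abundant member where none was called. It adds the 6 highest rises and 6 deepest falls per tissue, and the 5 most positive and 5 most negative interactions, among called genes with a mean FPKM of at least 5 in the higher group and no overlap between replicates. The text names only part of the genes the rule takes; this part was chosen for length after their values, and their values under other settings, were seen. Between WT tissues only lists are reported. Genes named outside the rule are said to be chosen after their values were seen.

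Promoters were searched for the evening element AAAATATCT, the CCA1-binding site AAAAATCT, the G-box CACGTG and the shuffled sequence AATAATACT. The search covered both strands of the 1000 bp upstream of 20870 genes in the TAIR10.1 reference. The lower coordinate of a gene equalled that of the reference for 99.9952% of the genes compared. The upper coordinate, from which promoters of genes on the minus strand were taken, was not compared. Fisher's exact test set called genes against the tested genes not called, with adjustment over 16 tests. The same tests on genes changed at least 2-fold were added after seeing the data, with their own adjustment over 16 tests.

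Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at FPKM 5, median-ratio scaling, quantile normalization within each tissue for single genes, a fit of each tissue alone, no variance trend, a replicate block, leaving out each library, a 2-fold minimum, camera with an estimated correlation, fry, and promoters of 500 and 1500 bp. Chosen after seeing the data were values scaled to the summed fragments, limma's voom on the recovered fragments, quantile normalization for the list tests, the 2-fold minimum in the promoter tests, interactions among genes with a mean FPKM of at least 1 in both tissues, and counts of genes called in both tissues with each tissue fitted alone. Promoters and figures were handled in Python 3.11.15 with SciPy 1.17.1 and matplotlib 3.10.9.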

Results

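Transcript levels were measured by RNA sequencing in shoots and roots of Arabidopsis seedlings grown for 8 days in constant white light of 15 µE at 22 °C. Wild-type Col-0 plants were compared with plants that overexpress CCA1, a MYB transcription factor of the circadian clock that peaks around dawn. The series title places the comparison in a study of how the clock acts on proton gradients and growth in different cell types. Each of the 4 groups held 3 libraries, with 39683894 to 44242304 fragments in WT shoots, 37216665 to 39814773 in CCA1-ox shoots, 37773138 to 45051329 in WT roots and 27142671 to 38537638 in CCA1-ox roots. Values are mean FPKM ± SD over n = 3 libraries, and all adjusted p-values for single genes are from limma with Benjamini-Hochberg adjustment.

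CCA1 (AT2G46830, chromosome 2, 19245591 to 19248915 on TAIR10) was higher in every CCA1-ox library than in every WT library of its tissue. In shoots it stood at 44.96 ± 0.202 FPKM in WT and 214 ± 1.98 in CCA1-ox (log2 fold change 2.23, SE 0.0317, adjusted p = 5.18e-15). Roots held 17.1 ± 0.838 FPKM in WT and 175 ± 4.36 in CCA1-ox (3.28, SE 0.0317, adjusted p = 4.78e-16).

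**Figure D1:**
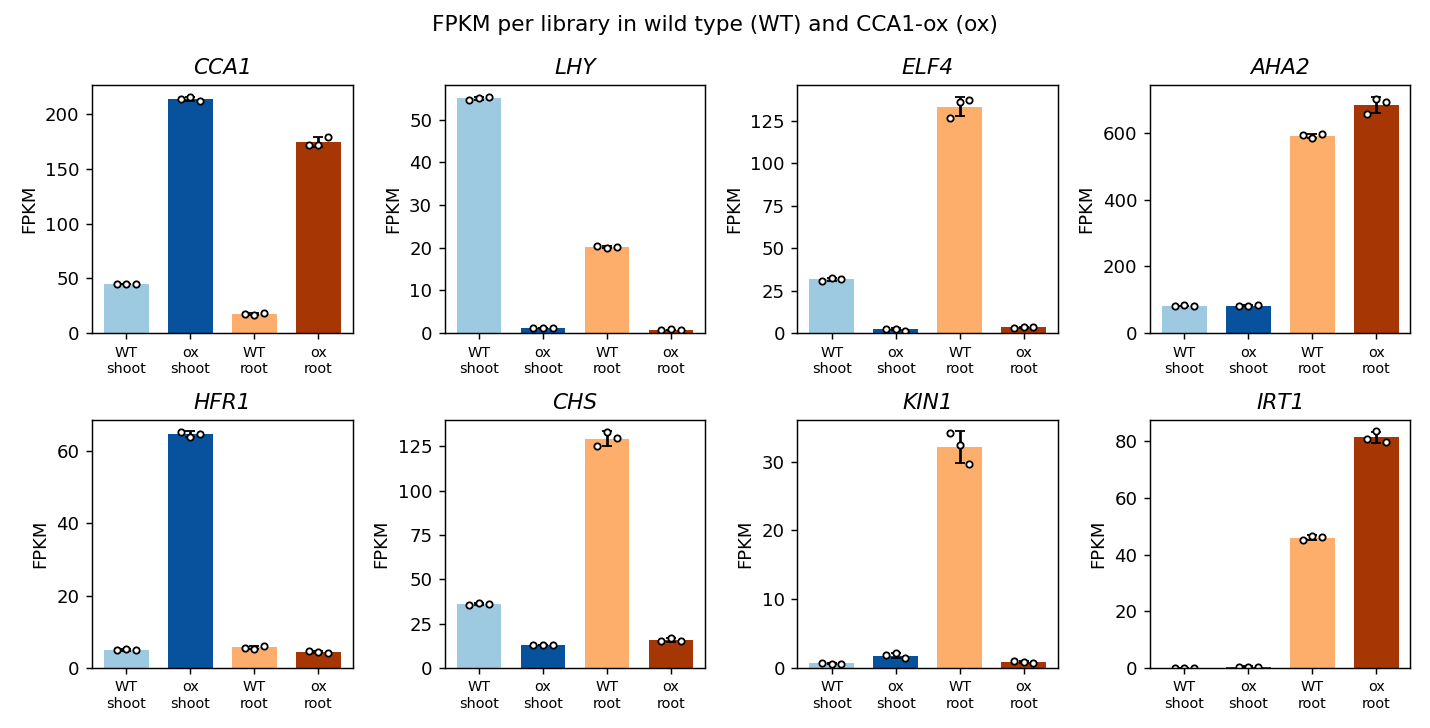
FPKM of 8 genes in the 12 libraries, with bars for the mean of 3 libraries, error bars for the SD and a point for each library, in wild type (WT) and CCA1-ox (ox) shoots and roots; each vertical axis starts at 0. CCA1 rises in both tissues and LHY, ELF4 and CHS fall in both. HFR1 rises in shoots, KIN1 rises in shoots and falls in roots, and IRT1 rises in roots. AHA2 is 81.6 and 81.5 FPKM in shoots, where its direction turns upward under 2 other scalings.

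In CCA1-ox shoots, clock genes moved in both directions, at a time of day that the labels do not give. LHY (AT1G01060, chromosome 1, 33365 to 37871), the close relative of CCA1, fell from 55.0 ± 0.326 to 1.14 ± 0.0793 FPKM (log2 fold change −4.71, SE 0.0504, adjusted p = 2.97e-16). RVE2 (AT5G37260) also fell (−2.22), while PRR7 (AT5G02810), a repressor of morning genes, rose from 12.6 ± 0.328 to 71.6 ± 2.13 FPKM (2.42). Of the 12 morning genes, 5 rose and 6 fell, and as a list they did not pass (adjusted p = 0.820). Evening genes were mostly lower, with 10 of 16 down and 4 up (mean log2 fold change −0.69, adjusted p = 0.0257). That list's adjusted p = 0.0652 with an estimated correlation, and with quantile normalization it did not pass either (0.0642). ELF4 (AT2G40080), a part of the evening complex, fell from 31.6 ± 0.805 to 2.22 ± 0.673 FPKM (−3.36), and FKF1 (AT1G68050), a blue-light receptor of the flowering pathway, from 8.72 ± 0.640 to 0.278 ± 0.111 (−2.93).

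Most light signalling, SAUR, and auxin synthesis and response genes rose in CCA1-ox shoots. HFR1 (AT1G02340), which restrains shade responses, rose from 4.93 ± 0.148 to 64.7 ± 0.741 FPKM (3.47), and PIF4 (AT2G43010), which promotes hypocotyl growth, from 18.6 ± 0.347 to 73.1 ± 0.503 (1.92). In the light signalling list 10 of 13 genes rose and 1 fell (mean 0.78, adjusted p = 0.000378), with an adjusted p = 0.0652 with an estimated correlation. Auxin synthesis and response genes rose in 18 of 26 cases and fell in 2 (mean 0.57, adjusted p = 2.19e-05), among them YUC8 (AT4G28720), an auxin synthesis enzyme (1.95), and IAA29 (AT4G32280, 1.56). SAUR genes, small auxin-induced genes of cell expansion, rose in 16 of 20 cases and fell in 1 (mean 0.67, adjusted p = 1.78e-05), with SAUR22 (AT5G18050) at 2.08 and SAUR36 (AT2G45210) at 1.299. Auxin carriers rose in 6 of 11 cases and fell in 1 (mean 0.37, adjusted p = 0.0198), LAX3 (AT1G77690) among them (1.18). Their adjusted p = 0.0841 with an estimated correlation. Xyloglucan endotransglucosylases, which remodel cell walls, rose in 11 of 20 cases and fell in 3 (mean 0.48, adjusted p = 0.0198, and adjusted p = 0.0777 with an estimated correlation), and the list did not pass scaled to the summed fragments (0.0665). Their strongest member, XTH24 (AT4G30270), rose from 17.3 ± 0.341 to 140 ± 1.49 FPKM (2.95). Expansins split into 6 up and 6 down of 17, and EXPA4 (AT2G39700) rose from 28.2 ± 1.77 to 127 ± 2.66 FPKM (2.13).

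Most phosphate starvation, glucosinolate and cold genes also rose in CCA1-ox shoots. Phosphate starvation genes rose in 8 of 10 cases and none fell (mean 1.25, adjusted p = 5.12e-05), with the phosphate sensor SPX1 (AT5G20150) at 2.098 and GDPD1 (SRG3 in the table, AT3G02040) at 2.58. Iron deficiency genes rose in 11 of 21 cases and fell in 2 (mean 0.20, adjusted p = 0.0328, and adjusted p = 0.0652 with an estimated correlation). Examples were the peptide gene IMA2 (AT1G47395), at 1.096, and the regulator BHLH38 (AT3G56970), at 0.85. Glucosinolate synthesis genes rose in 12 of 13 cases and none fell (mean 0.83, adjusted p = 1.27e-08), CYP79F2 (AT1G16400) by 1.90. All 13 measured cold and dehydration genes rose (mean 0.94, adjusted p = 6.67e-08), COR15A (AT2G42540) from 10.04 ± 0.404 to 39.4 ± 0.992 FPKM (1.87). Of 4 defence genes 3 rose and 1 fell (mean 1.58, adjusted p = 0.0198, and adjusted p = 0.0652 with an estimated correlation), VSP2 (AT5G24770) by 3.57. Starch genes rose in 8 of 13 cases and fell in 3 (mean 0.20, adjusted p = 0.0391, and adjusted p = 0.218 with an estimated correlation), and the list did not pass scaled to the summed fragments (0.0981). The amylase AMY3 (AT1G69830) rose by 1.28, and BAM9 (BMY3 in the table, AT5G18670) fell (−1.36).

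Most light-harvesting and flavonoid genes fell in CCA1-ox shoots. Light-harvesting and Rubisco small subunit genes fell in 17 of 25 cases and rose in 2 (mean −0.36, adjusted p = 0.000146). LHCB1.4 (LHB1B1 in the table, AT2G34430) fell from 4260 ± 55.2 to 1287 ± 9.42 FPKM (−1.73) and RBCS2B (AT5G38420) from 3407 ± 45.4 to 2018 ± 58.3 (−0.76). Both belong to near-identical gene families, so their single values are uncertain, and with quantile normalization the list did not pass (mean −0.13, adjusted p = 0.770). Flavonoid genes fell in 7 of 11 cases and rose in 1 (mean −0.48, adjusted p = 0.0205, and adjusted p = 0.0652 with an estimated correlation), with chalcone synthase CHS (TT4 in the table, AT5G13930) at −1.44. Cell division genes fell in 8 of 12 cases and none rose (mean −0.19, adjusted p = 0.0198, and adjusted p = 0.0652 with an estimated correlation), the mitotic kinase AUR1 (AT4G32830) among them (−0.43).

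Markers of the endodermis and xylem, most of them more abundant in WT roots than in WT shoots, were higher in CCA1-ox shoots. Endodermis markers rose in 8 of 9 cases and 1 fell (mean 0.75, adjusted p = 0.00102), PER64 (AT5G42180) by 1.54 and CASP1 (AT2G36100) by 1.14. All 8 xylem markers rose (mean 0.82, adjusted p = 1.45e-05), XCP1 (AT4G35350) from 13.5 ± 0.554 to 30.2 ± 0.975 FPKM (1.101) and LAC4 (IRX12 in the table, AT2G38080) from 7.42 ± 0.994 to 17.02 ± 0.590 (1.105). None of the 12 root hair markers or 3 root cap markers passed. Guard cell markers split into 2 up and 5 down of 9 (mean −0.16, adjusted p = 0.267), with the regulator FAMA (FMA in the table, AT3G24140) at −0.56 and the potassium channel KAT1 (AT5G46240) at 0.46.

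Among proton pumps of the plasma membrane, 8 of 11 AHA genes were measured, and in CCA1-ox shoots 3 fell and 1 rose. AHA3 (HA3 in the table, AT5G57350) went from 47.7 ± 0.358 to 37.9 ± 1.15 FPKM (−0.32, adjusted p = 1.16e-05) and AHA11 (AT5G62670) from 40.1 ± 0.721 to 32.8 ± 0.402 (−0.28, adjusted p = 7.93e-05). AHA7 (AT3G60330) fell (−0.22, adjusted p = 0.0187), but not without WT shoot replicate 2 (0.0675), WT shoot replicate 3 (0.0822) or CCA1-ox shoot replicate 3 (0.0533). Its call was also lost with a pseudocount of 5 (0.0598), in the fit of shoots alone (0.0634) and scaled to the summed fragments (0.0820). AHA4 (AT3G47950) rose from 0.584 ± 0.0891 to 1.003 ± 0.0433 FPKM (0.34, adjusted p = 0.000204), a call lost with quantile normalization (adjusted p = 0.575). The abundant AHA1 (AT2G18960), at 144 ± 1.74 and 139 ± 1.304 FPKM, and AHA2 (AT4G30190), at 81.6 ± 0.876 and 81.5 ± 1.42, did not pass (adjusted p = 0.0932 and 0.964), but both were called higher with quantile normalization (0.10 and 0.11) and scaled to the summed fragments (0.058 and 0.11). AHA1 was called lower without CCA1-ox root replicate 1 (0.0485), in the fit of shoots alone (0.0295) and with voom (0.0247). AHA5 (AT2G24520, −0.18, adjusted p = 0.0551) and AHA8 (AT3G42640, −0.12, adjusted p = 0.0899) did not pass and were called lower with quantile normalization (0.0126 and 0.00653). AHA5 was also called lower with a pseudocount of 5 (0.0269), a filter at FPKM 5 (0.0454) and voom (0.00677), and without CCA1-ox shoot replicate 3 (0.0258), WT root replicate 2 (0.0434), CCA1-ox root replicate 1 (0.0444) or CCA1-ox root replicate 3 (0.0485), and AHA8 without WT shoot replicate 1 (0.0483). AHA4, AHA7, AHA8 and AHA11 overlap genes on the other strand. Vacuolar proton pumps fell in 14 of 29 cases and rose in 2 (mean −0.063, adjusted p = 0.0391, and adjusted p = 0.0652 with an estimated correlation), but their mean turned upward with quantile normalization (0.023) and scaled to the summed fragments (0.043). VHA-c1 (AVA-P1 in the table, AT4G34720) was at −0.35.

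Among the highest rises in CCA1-ox shoots were genes outside the lists. DR4 (AT1G73330), a protease inhibitor gene, rose from 6.42 ± 0.984 to 653 ± 23.2 FPKM (6.47), MLP34 (AT1G70850) from 3.07 ± 0.507 to 293 ± 4.14 (6.18), AT5G37990 from 1.04 ± 0.399 to 184 ± 5.71 (6.52) and AT5G03545 from 0.378 ± 0.198 to 143 ± 9.20 (6.71). AT2G01422 (chromosome 2, 183940 to 184734) rose from 0.0763 ± 0.0462 to 93.2 ± 1.41 FPKM (6.45). MRD1 (AT1G53480, chromosome 1, 19963047 to 19964712), which overlaps HEI10 (AT1G53490) on the other strand, fell from 34.6 ± 0.336 to 0.0856 ± 0.00307 FPKM (−5.04). The histone demethylase gene JMJD5 (AT3G20810), a clock-associated gene, fell from 52.8 ± 1.65 to 2.71 ± 0.497 (−3.87), and AT1G13650 from 20.2 ± 0.747 to 1.58 ± 0.348 (−3.05).

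Of 20975 genes tested, 11637 changed in CCA1-ox shoots, 5582 higher and 6055 lower, and 957 of them by at least 2-fold, 797 higher and 160 lower. Of the called genes 3734 (32.1%) changed by under 0.25 log2. The split of called genes depended on scaling, with 48.0% higher as deposited and 66.0% scaled to the summed fragments. Of the 30 lists 18 passed, 13 up and 5 down, and 8 held with an estimated correlation: SAUR genes, phosphate starvation, auxin synthesis and response, light harvesting, glucosinolates, cold, endodermis and xylem. The other 12 lists did not pass (adjusted p = 0.266 to 0.933). Among these were nutrient uptake (8 up, 8 down of 19, with the nitrate reductase gene NIA2, AT1G37130, at −0.81), cation/H+ exchangers (5 up, 1 down of 12, with CAX1, AT2G38170, at −0.68) and flowering genes (4 up, 3 down of 8, with COL2, AT3G02380, at −1.94 and CDF3, AT3G47500, at 1.402). Aquaporins (9 up, 7 down of 19) and heat shock genes (1 up, 1 down of 3) did not pass either, with TIP1;1 (GAMMA-TIP in the table, AT2G36830) at −0.80 and HSP18.2 (AT5G59720) at 1.12. Clade D phosphatases (4 up, 2 down of 9) had a median of −0.016 and a mean of 0.25, and heat shock genes a median of −0.14 and a mean of 0.27. For aquaporins camera and fry gave opposite directions, and the list was called higher with quantile normalization (0.10, adjusted p = 0.0172). Adjusted over the list alone, the counts differed in 8 lists: 4 AHA genes lower, 17 SAUR, 12 iron, 5 flowering, 5 light-harvesting and 13 glucosinolate genes higher, 8 aquaporins lower and 6 guard cell markers lower.

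**Figure D2:**
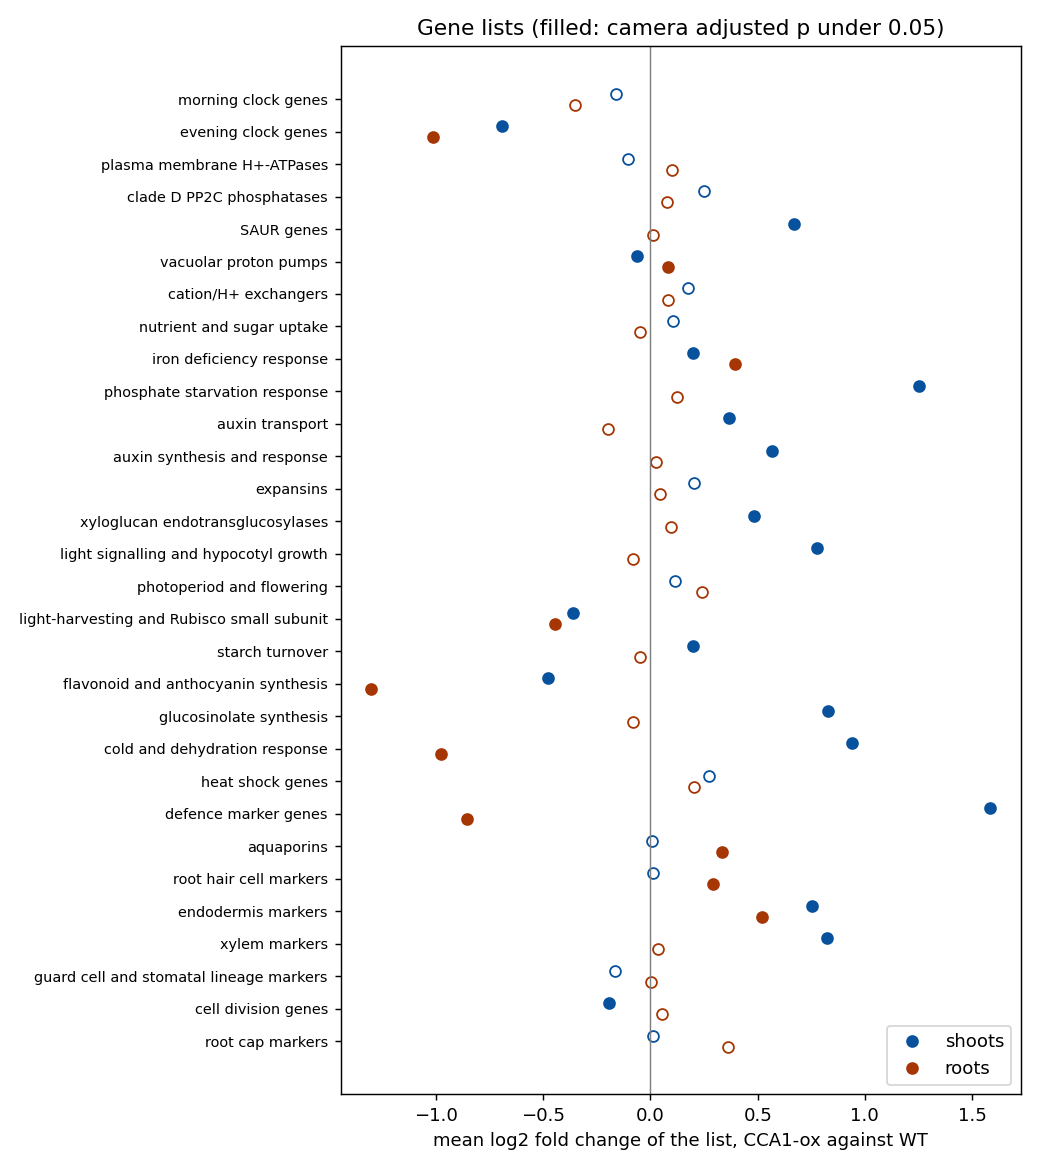
Mean log2 fold change (CCA1-ox against WT, log2(FPKM + 1) scale) of the 30 gene lists in shoots (blue) and roots (brown), with filled points for lists past the camera test at adjusted p under 0.05 and open points for the others. Cold and dehydration genes lie at 0.94 in shoots and −0.98 in roots, and the vacuolar proton pump mean in shoots turns upward under 2 other scalings.

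In CCA1-ox roots, evening clock genes were also mostly lower. Of 16 evening genes 11 fell and 4 rose (mean −1.01, adjusted p = 1.04e-06), with ELF4 down from 133 ± 5.80 to 3.39 ± 0.255 FPKM (−4.94), PRR5 (AT5G24470) down from 15.5 ± 0.551 to 2.66 ± 0.359 (−2.17) and FKF1 at −2.18. LHY fell from 20.2 ± 0.218 to 0.721 ± 0.101 FPKM (−3.62) and RVE2 from 120 ± 3.81 to 6.64 ± 0.547 (−3.99), and 4 of 12 morning genes rose and 6 fell (adjusted p = 0.152).

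Most flavonoid and cold genes fell in CCA1-ox roots. Flavonoid genes fell in 7 of 11 cases and none rose (mean −1.30, adjusted p = 5.00e-08), CHS from 129 ± 3.96 to 15.7 ± 1.23 FPKM (−2.97) and chalcone isomerase CHI (TT5 in the table, AT3G55120) from 19.9 ± 0.126 to 1.77 ± 0.481 (−2.93). Cold and dehydration genes fell in 10 of 13 cases and none rose (mean −0.98, adjusted p = 2.82e-08), with KIN1 (AT5G15960) down from 32.1 ± 2.29 to 0.837 ± 0.130 FPKM (−4.17), its near-identical neighbour KIN2 (AT5G15970) at −2.62 and RD29A (LTI78 in the table, AT5G52310) at −1.82. Light-harvesting and Rubisco genes, at low levels in roots, fell in 11 of 25 cases and rose in 3 (mean −0.45, median −0.087, adjusted p = 2.29e-05). LHCB1.5 (LHB1B2 in the table, AT2G34420) rose from 35.5 to 65.8 FPKM and LHCA4 (AT3G47470) from 23.2 to 34.8, both chosen after their values were seen. Of the 23 members abundant in shoots, they were the most abundant in WT roots. LHCB1.3 (CAB1 in the table, AT1G29930) fell from 13.1 ± 1.16 to 0.718 ± 0.0793 FPKM (−3.03) and RBCS1A (AT1G67090) from 4.61 ± 0.626 to 0.225 ± 0.104 (−2.19). Of 4 defence genes 2 fell (mean −0.85, adjusted p = 0.0252, and adjusted p = 0.0942 with an estimated correlation), but not with a pseudocount of 0.1 (0.0559) or scaled to the summed fragments (0.0815), VSP2 from 4.97 ± 0.328 to 0.175 ± 0.0699 FPKM (−2.34).

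Most iron deficiency, aquaporin and endodermis genes rose in CCA1-ox roots. Iron deficiency genes rose in 16 of 21 cases and fell in 2 (mean 0.40, adjusted p = 6.88e-07), the iron transporter IRT1 (AT4G19690) from 45.9 ± 0.841 to 81.4 ± 1.93 FPKM (0.81), the reductase FRO2 (AT1G01580) from 11.2 ± 0.183 to 22.5 ± 0.844 (0.94) and CYP82C4 (AT4G31940) from 11.1 ± 0.137 to 29.8 ± 1.14 (1.34). Aquaporins rose in 16 of 19 cases and fell in 2 (mean 0.33, adjusted p = 2.82e-08, and adjusted p = 0.140 with an estimated correlation), PIP1;1 (PIP1A in the table, AT3G61430) from 235 ± 2.56 to 425 ± 7.91 FPKM (0.85) and TIP2;1 (DELTA-TIP, AT3G16240) from 90.6 ± 4.84 to 174 ± 9.97 (0.93). All 9 endodermis markers rose (mean 0.52, adjusted p = 3.92e-05), CASP4 (AT5G06200) by 0.76 and CASP2 (AT3G11550) by 0.62. Root hair markers rose in 9 of 12 cases and fell in 1 (mean 0.29, adjusted p = 0.00397, and adjusted p = 0.0942 with an estimated correlation), but not with a pseudocount of 0.1 (0.105), with RSL2 (AT4G33880) at 0.70 and PRP1 (AT1G54970) at −0.58. Root cap markers rose in 2 of 3 cases without passing as a list (adjusted p = 0.116), BRN1 (NAC015 in the table, AT1G33280) by 0.60.

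Proton pumps in CCA1-ox roots were led by AHA2, the most abundant H+-ATPase transcript there. AHA2 went from 591 ± 6.16 to 683 ± 24.5 FPKM (0.21, adjusted p = 2.97e-05), a call lost with quantile normalization (0.072, adjusted p = 0.124). AHA7 rose from 5.86 ± 0.177 to 10.6 ± 0.416 FPKM (0.75, adjusted p = 2.205e-06) and AHA3 fell from 13.7 ± 0.450 to 11.3 ± 0.585 (−0.25, adjusted p = 0.000249). AHA1 (0.063, adjusted p = 0.0526), AHA4 (0.979), AHA5 (0.681), AHA8 (0.407) and AHA11 (0.869) did not pass, and the 8 genes as a list did not either (adjusted p = 0.494). AHA1 passed without CCA1-ox root replicate 1 (0.00968) and with voom (0.00212), and its direction turned downward with quantile normalization and scaled to the summed fragments. Vacuolar proton pumps rose in 12 of 29 cases and fell in 2 (mean 0.083, adjusted p = 0.00969), VHA-E3 (AT1G64200) by 0.30, but the list did not pass with quantile normalization (0.0096, adjusted p = 0.974) or scaled to the summed fragments (0.019, adjusted p = 0.255).

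Beyond the lists, AT2G01422 rose in CCA1-ox roots from 0.0510 ± 0.0424 to 57.1 ± 0.684 FPKM (5.79), ALD1 (AT2G13810), which makes a precursor of the immune signal pipecolic acid, from 3.25 ± 0.261 to 20.8 ± 2.197 (2.36), and the neighbours AT5G36130 and CYP716A2 (AT5G36140) by 2.15 and 2.14. MRD1 fell from 36.3 ± 0.439 to 0.188 ± 0.0734 FPKM (−4.98) and JMJD5 from 19.6 ± 0.256 to 0.420 ± 0.0423 (−3.86).

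Of the 20975 genes 7612 changed in CCA1-ox roots, 4372 higher and 3240 lower, and 306 by at least 2-fold, 94 higher and 212 lower; 3259 of the called genes (42.8%) changed by under 0.25 log2. As deposited 57.4% of called genes were higher, against 38.8% scaled to the summed fragments. Of the 30 lists 10 passed, 5 up and 5 down, and 7 held with an estimated correlation: evening clock genes, vacuolar pumps, iron, light harvesting, flavonoids, cold and endodermis. The other 20 did not pass (adjusted p = 0.0829 to 0.912). Auxin carriers (2 up, 4 down of 11, PIN5, AT5G16530, at −1.46, called lower as a list with quantile normalization at an adjusted p of 0.0377), nutrient uptake (6 up, 7 down of 19, with the sucrose carrier SUC2, AT1G22710, at −1.23 and the sulfate carrier SULTR1;2, AT1G78000, at 0.90) and expansins (8 up, 5 down of 17, EXPA8, AT2G40610, at 1.16, EXPA10, AT1G26770, at −1.25 and EXPA4 at −0.75) went both ways. So did xyloglucan endotransglucosylases (13 up, 5 down of 20, XTH31, AT3G44990, at −0.83), auxin synthesis and response (6 up, 4 down of 26, IAA2, AT3G23030, at −0.40), starch (4 up, 4 down of 13), light signalling (2 up, 4 down of 13, HY5, AT5G11260, at −0.70), flowering (4 up, 2 down of 8, FLC, AT5G10140, at 1.12) and glucosinolates (4 up, 4 down of 13). Glucosinolate genes had a median of 0.013 and a mean of −0.081, and SAUR genes (2 up, 2 down of 20) a mean of 0.011 with a test direction downward. Guard cell markers had a mean of 0.00078 and a test direction downward as well. Phosphate starvation (3 up of 10, SPX1 at 0.31), cation/H+ exchangers (4 up of 12, CAX4, AT5G01490, at 0.62), clade D phosphatases (3 up of 9), heat shock (2 up of 3, HSP90.1, AT5G52640, at 0.70) and cell division genes (3 up of 12) had no member lower. PCNA1 (AT1G07370) rose by 0.17, a call lost without WT root replicate 1 (adjusted p = 0.0647) or CCA1-ox root replicate 2 (0.0667). Of 8 xylem markers, CESA4 (AT5G44030) rose (0.13, adjusted p = 0.0297), but not without WT root replicate 1 (0.0579), 2 (0.0794) or 3 (0.0773) or CCA1-ox root replicate 2 (0.110) or 3 (0.0865), and no guard cell marker was called. Scaled to the summed fragments, CESA4 (0.255) and PCNA1 (0.105) were not called either, nor was CESA4 with quantile normalization (0.0842). Adjusted over the list alone, the counts differed in 9 lists: 3 AHA genes higher, 1 SAUR gene lower, 14 vacuolar pump and 7 auxin response genes higher, 13 light-harvesting, 5 starch and 1 heat shock genes lower, 3 aquaporins lower and 0 xylem markers higher.

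Cold genes changed in opposite directions in the tissues, with a mean of 0.94 in CCA1-ox shoots and −0.98 in CCA1-ox roots. Glucosinolate genes rose in shoots and went both ways in roots (means 0.83 and −0.081). Phosphate starvation genes rose less in roots (1.25 in shoots and 0.12 in roots). All 13 cold and dehydration genes had a lower effect in roots than in shoots (mean interaction −1.92, adjusted p = 1.13e-11). So did 12 of 13 glucosinolate genes (mean −0.91, adjusted p = 3.16e-09) and 7 of 10 phosphate starvation genes (mean −1.13, adjusted p = 0.000220). VSP2 had an interaction of −5.91, SE 0.122, with opposite calls in the tissues, and PDF2.1 (AT2G02120), a defensin gene, went from 0.374 ± 0.119 to 9.82 ± 1.87 FPKM in shoots and from 259 ± 10.5 to 29.1 ± 3.08 in roots (−6.08). DR4 (−6.34), AT5G37990 (−6.32) and MLP34 (−6.04) rose in shoots and did not pass in roots, where DR4 stood at 1342 ± 34.2 FPKM in WT and 1469 ± 24.9 in CCA1-ox. AT1G13650 and AT4G13575, which overlaps a gene on its own strand, fell in shoots and were listed at 0 in all root libraries, and ALD1 was listed at 0 in all shoot libraries. SWEET2 (AT3G14770), a sugar carrier, fell in shoots from 22.4 ± 1.68 to 4.61 ± 0.363 FPKM and stood at 32.9 ± 1.24 and 37.6 ± 1.36 in roots (2.25), and AT4G04415 fell in shoots from 5.39 ± 1.11 to 0.761 ± 0.510 (2.25).

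The interaction passed for 10636 genes, 5705 with a higher and 4931 with a lower effect in roots, and 1209 by at least 2-fold, 230 higher and 979 lower. As deposited 53.6% of these had the higher effect in roots, against 29.0% scaled to the summed fragments, a scaling that moved the median interaction of all genes from 0.037 to −0.11. Of the 30 lists 17 passed, 5 up and 12 down, and 11 held with an estimated correlation. Evening clock (adjusted p = 0.0559), iron (0.0559), cell division (0.0559), starch (0.236), aquaporins (0.274) and root hair (0.203) did not with an estimated correlation. SAUR genes did not pass with voom (0.489), and vacuolar pumps not with quantile normalization (0.464) or scaled to the summed fragments (0.380), where their mean turned downward. Of 20 SAUR genes 16 had a mean FPKM under 1 in both root groups, so their interaction rests mainly on the change in shoots. Among the 17141 genes with a mean FPKM of at least 1 in both tissues, a set chosen after seeing the data, 8717 passed and 15 lists did. There SAUR genes (4 left, mean −0.29, adjusted p = 0.450) and iron (14 left, −0.026, 0.501) did not pass, xyloglucan endotransglucosylases did (14 left, −0.71, 0.00756), and no root hair marker was left. Cation/H+ exchangers and light harvesting had opposite directions in camera and fry. Expansins had a median of 0.17 and a mean of −0.16, and heat shock genes a median of 0.43, a mean of −0.070 and a test direction upward. Adjusted over the list alone, counts differed in 5 lists: 4 evening clock genes, 5 AHA genes and 9 expansins higher, and 8 phosphate and 10 light signalling genes lower.

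Called genes were counted in both tissues, with the counts that independent lists would give beside them for scale. Higher in both were 1559 genes (1164 from independent lists), lower in both 1225 (935), higher in shoots and lower in roots 1050 (862) and lower in shoots and higher in roots 1069 (1262). These calls come from 1 fit with 1 variance per gene and are not independent, so the differences from independent lists are not a test. With each tissue fitted alone, an alternative added after seeing the data, the counts were 1503 (1039), 1037 (791), 950 (718) and 860 (1145). With at least 2-fold in each tissue the counts were 16, 29, 32 and 0, and CCA1, LHY, ELF4, RVE2, PRR7, FKF1, MRD1, JMJD5 and AT2G01422 were among the 45 that moved the same way. Across genes, which are not independent replicates, fold changes in the tissues had r = 0.131, rho = 0.110 and a covariance of 0.0197.

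**Figure D3:**
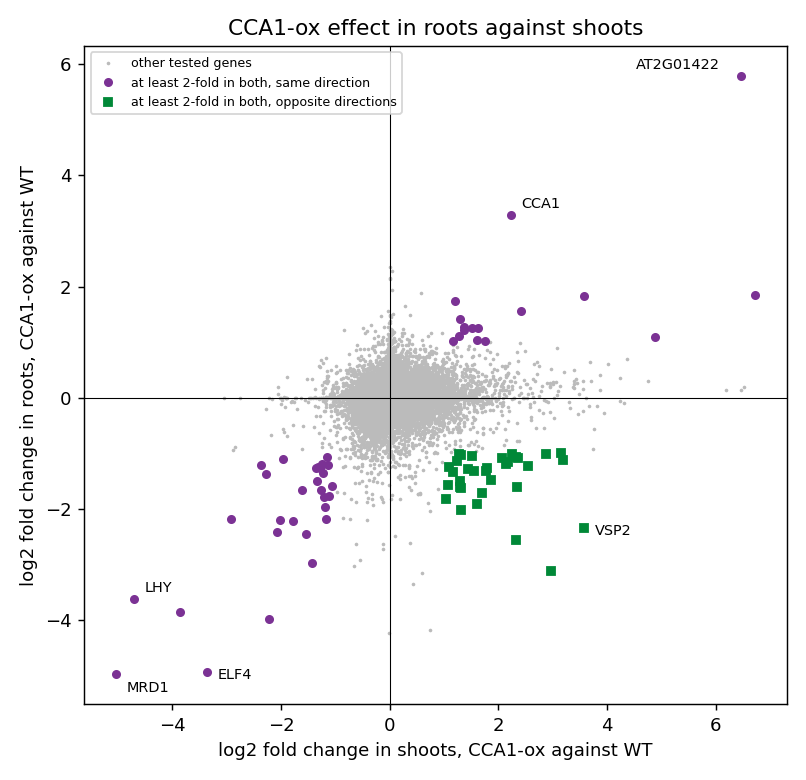
Log2 fold change of each of the 20975 tested genes in CCA1-ox against WT, with shoots on the horizontal and roots on the vertical axis; 45 genes that changed at least 2-fold the same way in both tissues are purple and 32 that changed in opposite directions are green. AT2G01422 and CCA1 lie high in both tissues, LHY, ELF4 and MRD1 low in both.

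WT roots were compared with WT shoots to place the genotype effects against the tissues themselves, and they differed in 18285 of 20975 genes, 9510 higher and 8775 lower in roots, and 8238 by at least 2-fold, 4292 higher and 3946 lower. All 25 light-harvesting and Rubisco genes were lower in roots (mean −8.73, adjusted p = 4.73e-14) and all 12 root hair markers higher (mean 3.44, adjusted p = 6.49e-05). Guard cell markers were lower in all 9 cases (mean −2.75, adjusted p = 0.000719). Endodermis markers were higher in 8 of 9 cases (mean 2.99, adjusted p = 0.00769, and adjusted p = 0.0537 with an estimated correlation). Of the 30 lists 10 passed, and SAUR genes, light harvesting, root hair and guard cell markers held with an estimated correlation. Mean and median differed in sign for evening clock genes (−0.11 and 0.070), clade D phosphatases (−0.0026 and 0.12), auxin synthesis and response (0.29 and −0.019), expansins (−0.35 and 0.42) and aquaporins (0.21 and −0.15), and camera and fry differed in direction for iron deficiency, phosphate starvation, clade D phosphatases and expansins. As deposited 52.0% of called genes were higher in roots, against 65.6% scaled to the summed fragments, where the median of all genes moved from 0.035 to 0.33.

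The evening element AAAATATCT, to which CCA1 is known to bind, lay in the 1000 bp upstream of 10.11% of genes lower in CCA1-ox roots and 6.63% of genes not called (odds ratio 1.58, Fisher's exact test, two-sided, adjusted p = 7.60e-10). Genes higher in CCA1-ox shoots also held it more often, 9.11% against 6.35% (1.48, adjusted p = 5.43e-09). Genes lower in shoots (6.33%, odds ratio 0.998, adjusted p = 1) and higher in roots (6.22%, 0.935, adjusted p = 0.513) did not pass. Among genes changed at least 2-fold, a set of 16 tests added after seeing the data and adjusted on its own, those lower in shoots did pass, with the element upstream of 22 of 157 (14.0%, 2.41, adjusted p = 0.00310). So did those higher in shoots (9.41%, 1.53, adjusted p = 0.00428) and lower in roots (21.2%, 3.797, adjusted p = 9.90e-11), but not those higher in roots (11.7%, 1.87, adjusted p = 0.105). The shuffled sequence AATAATACT was also more frequent upstream of genes higher in shoots (1.24, adjusted p = 0.0315, but 0.130 in 500 bp) and in roots (1.23, adjusted p = 0.0399). CCA1-binding sites AAAAATCT were more frequent upstream of genes higher in shoots (1.204, adjusted p = 2.22e-05) and roots (1.21, adjusted p = 2.90e-05). Their excess upstream of genes lower in roots (1.12, adjusted p = 0.0399) did not pass in 500 bp (0.141) or 1500 bp (0.0851). The G-box CACGTG was more frequent upstream of genes higher in shoots (1.27, adjusted p = 1.07e-06) and lower in roots (1.28, adjusted p = 1.27e-05). With the 2-fold minimum only 2 results of these 3 motifs passed, CCA1-binding sites in genes higher in shoots (1.35, adjusted p = 0.00310) and the G-box in genes lower in roots (2.15, adjusted p = 3.11e-05). The other 5 did not, in smaller sets and at odds ratios of 1.404 and 1.41 for CCA1-binding sites (lower and higher in roots), 1.24 for the G-box (higher in shoots) and 1.45 and 1.25 for the shuffled sequence (higher in shoots and in roots).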

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

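The tests of carried-over tissue and of scaling below, their split by marker list, and the comparison among genes measured in both tissues were chosen only after the results were seen. The counts, lists and genes given by value were singled out because the effect of CCA1-ox differed between roots and shoots by the interaction test. The patterns weighed at the end are effects tested within 1 tissue. In camera's interaction test xylem markers passed (mean −0.79, adjusted p = 2.66e-05), but endodermis markers (0.248) and light-harvesting genes (0.980) did not. Endodermis markers rose as a list in both shoots (mean 0.75) and roots (0.52). The mean of light-harvesting genes was lower in both (−0.36 and −0.45), though some members rose. Their fall in shoots did not pass with quantile normalization. No test for an outlying library was run on groups of 3; fits without each library are given with the processing.

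The interaction passed for 10636 genes, and 1 of 100 splits of the libraries gave as many, the real one. The highest of the others gave 6533, and some of these splits keep the real grouping of 1 tissue. Not every possible split was drawn. The splits exchange genotype labels within each tissue, so they stand for no genotype effect in either tissue, not for an equal effect in both. They therefore cannot decide whether chance gave the interaction. The labels name no separate cultures, so chance differences between cultures are not excluded. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05: 1 split reached the real value in each, with 11637 genes in shoots and 0 in the highest other, 7612 in roots and 1 in the highest other, and 18285 between WT tissues and 0 in the highest other.

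List means of the root effect less the shoot effect were lower in roots for defence (−2.44), cold (−1.92), phosphate starvation (−1.13), glucosinolates (−0.91), light signalling (−0.86), flavonoids (−0.82), xylem (−0.79), SAUR genes (−0.66), auxin transport (−0.57), auxin synthesis and response (−0.54), evening clock genes (−0.32) and starch (−0.25). A lower value need not be a weaker effect: evening clock and flavonoid means fell in both tissues, and by more in roots. List means were higher in roots for aquaporins (0.33), root hair markers (0.28), cell division (0.25), iron (0.20) and vacuolar pumps (0.15). Vacuolar pumps turned to −0.014 with quantile normalization and −0.025 scaled to the summed fragments, and root hair markers to −0.16 with voom. With an estimated correlation 6 of these lists did not pass: evening clock genes, iron and cell division (adjusted p = 0.0559 each), starch (0.236), aquaporins (0.274) and root hair markers (0.203). The value of members under 1 FPKM in both groups of a tissue rests mainly on the other tissue: 16 of 20 SAUR genes in roots, and 6 of 21 iron genes in shoots. Among genes with a mean of at least 1 FPKM in both tissues neither list passed (means −0.29 and −0.026, adjusted p = 0.450 and 0.501), and root hair markers had no member left. There the means of lists that kept their call moved by over 1.5 times for defence (2 of 4 genes left, −4.54), flavonoids (5 of 11 left, −1.62) and starch (11 of 13 left, −0.47).

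Of the 95 named genes 84 had an interaction, 36 positive and 48 negative, and 19 were called in opposite directions in the tissues. A high share is built in, as the rule takes genes for large changes or interactions. Over all tested genes 10636 of 20975 (50.7%) passed the interaction. Of the 84, 24 had a mean under 1 FPKM in both groups of 1 tissue, so that their value rests mainly on the other tissue. In roots these were SAUR22, IAA29, PIF4, COL2, LHCB1.4, RBCS2B, COR15A, FAMA, KAT1, AT1G13650, AT4G13575 and AT4G04415, and in shoots CAX4, SULTR1;2, CYP82C4, FRO2, IRT1, PIN5, RSL2, PRP1, BRN1, ALD1, AT5G36130 and CYP716A2. Under other settings 23 of the 84 lost their call or turned, 11 of them with voom alone. Clock and proton pump genes with a positive value were LHY (1.08), CCA1 (1.05), AHA7 (0.97), FKF1 (0.75), AHA11 (0.27), AHA2 (0.21) and AHA1 (0.11). AHA1 turned to −0.13 with quantile normalization and −0.061 scaled to the summed fragments and was not called without a variance trend (adjusted p = 0.0632). AHA2 turned to −0.040 with quantile normalization and was not called scaled to the summed fragments (0.416), nor was AHA11 (0.179), and FKF1 was not called with a pseudocount of 0.1 (0.243) or voom (0.823). Those with a negative value were RVE2 (−1.77), ELF4 (−1.57), PRR5 (−1.44), PRR7 (−0.85) and AHA4 (−0.34), the last not called with quantile normalization (0.782). Growth, light and auxin genes mostly had a negative value: HFR1 (−3.76), XTH24 (−3.21), EXPA4 (−2.88), XTH31 (−2.37), SAUR22 (−2.08), YUC8 (−1.99), PIF4 (−1.71), PIN5 (−1.65), IAA29 (−1.60), IAA2 (−1.58), SAUR36 (−1.47), LAX3 (−0.96) and EXPA10 (−0.65), with EXPA8 at 0.41. A negative value is not always a smaller change in roots. PIN5 fell in roots from 2.74 to 0.357 FPKM and stood at 0.701 and 0.945 in shoots, and EXPA10 also fell more in roots. EXPA8 (0.426) and EXPA10, which turned to 0.060, were not called with a pseudocount of 5, and PIF4 turned to 0.19 with voom. SAUR22 was not called with voom (0.0960).

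Nutrient and transport genes ranged from GDPD1 (−2.41), SPX1 (−1.79), IMA2 (−1.12) and SUC2 (−0.71) up to CYP82C4 (1.35), SULTR1;2 (1.23), TIP2;1 (1.21), TIP1;1 (1.17), CAX1 (0.86), PIP1;1 (0.79), NIA2 (0.71), CAX4 (0.66), FRO2 (0.63), IRT1 (0.43) and VHA-c1 (0.38). IRT1 turned to −0.68 with a pseudocount of 0.1 and −1.47 with voom, and FRO2 was not called with the former (0.863) and turned to −0.24 with the latter. CYP82C4 (0.0928) and CAX4 (0.218) were not called with voom. Metabolic and flowering genes were at LHCB1.4 (1.73), COL2 (1.33), BAM9 (1.04), RBCS2B (0.75), CDF3 (−0.79), AMY3 (−0.96), CHS (−1.53), RBCS1A (−1.77), LHCB1.3 (−2.37), CHI (−2.38) and CYP79F2 (−2.51). COL2 was not called with a pseudocount of 0.1 (0.443) and turned to −0.26 with voom. LHCB1.4 (0.0850) and RBCS2B (0.670) were not called with voom. Stress genes were at VSP2 (−5.91), KIN1 (−4.92), KIN2 (−3.00), RD29A (−2.85), COR15A (−1.87), HSP18.2 (−1.48) and HSP90.1 (0.84). COR15A was not called with voom (0.193).

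Cell type and division genes were at XCP1 (−1.06), LAC4 (−1.14), PER64 (−1.02), CESA4 (−0.78), CASP1 (−0.65), PRP1 (−0.58), KAT1 (−0.47), AUR1 (0.47), PCNA1 (0.49), FAMA (0.56), BRN1 (0.57) and RSL2 (0.70). BRN1 was not called with a pseudocount of 0.1 (adjusted p = 0.215) and turned to −0.16 with voom. PRP1 (0.490), KAT1 (0.413), FAMA (0.343) and RSL2 (0.575) were not called with voom. Genes taken for their size were DR4 (−6.34), AT5G37990 (−6.32), PDF2.1 (−6.08), MLP34 (−6.04), AT5G03545 (−4.87), AT2G01422 (−0.66), CYP716A2 (2.14), AT5G36130 (2.15), SWEET2 (2.25), AT4G04415 (2.25), ALD1 (2.36), AT4G13575 (2.76) and AT1G13650 (3.05). AT2G01422 was not called with a pseudocount of 0.1 (adjusted p = 0.170) or with voom (0.925).

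Endodermis and xylem markers and several root-abundant genes were higher in CCA1-ox shoots. Root tissue with the transcript makeup of whole roots, carried into those samples, would raise root hair and root cap markers by a like share. These gained a median of 0% of their WT root level (SD 0 over replicates, 15 genes). The 15 endodermis and xylem markers pooled gained 17.1% (SD 5.58). That comparison did not decide at a margin of 2 SD. Its prediction named only the replicate spread, and a margin of 1 SD would have been met. Taken list by list, a split made after that outcome, endodermis markers gained 7.87% (SD 0.841) and xylem markers 49.9% (SD 2.70). For each list this argues against carried tissue with the makeup of whole roots. It cannot decide on a carried part of the root that is low in root hair and root cap transcripts. The marker mean was 0.69 log2 in the lower of 2 rescalings, to the summed fragments and by quantiles. Its SE of 0.102 is over genes, which are not independent replicates. These rescalings moved the median of all genes from −0.0083 to 0.064 and −0.051. Shifts of that size are far below the marker mean, so these rescalings could hardly have removed it. The values show only that these 2 rescalings do not account for the marker mean, a reading that does not rest on the spread between libraries. The 11 abundant root-specific genes, chosen after their values were seen, gained from 0.0169% in DOX1 to 48.4% in DR4. Of them 36.4% lay within 4-fold of the median gain of 1.5004% (at most 45.5% in any library, with CCA1-ox roots as the source). These unlike gains argue against carried tissue with the makeup of whole roots as the whole source. A small share, or a carried part of the root with another makeup, stays open. A difference between the genotypes in the shoot's own inner tissues, or in where shoot and root were parted, may remain as a hypothesis and was not tested.

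As a list, light-harvesting and Rubisco genes had a negative mean log2 fold change in CCA1-ox roots (−0.45), with a median of −0.087. Not every member fell. LHCB1.5 (35.5 to 65.8 FPKM) and LHCA4 (23.2 to 34.8), the most abundant in WT roots of the 23 members abundant in shoots, rose. Shoot RNA carried into WT roots would cost the members abundant in shoots a like share of their shoot level. Of 23 such members 8.70% lay within 4-fold of the median share. That median was only 0.0051%, so few members could lie so near it. Some members lost like shares, such as LHCB1.3 (0.071%) and LHCB2.1 (0.066%), but 8 lost nothing or rose. Shares ran from −0.43%, a rise, to 0.94%, which argues against carried shoot RNA as the whole source. Values of near-identical members are uncertain. The list mean was −0.42 log2 in the higher of the same 2 rescalings. Its SE of 0.167 is over genes, which are not independent replicates. The rescalings moved the median of all genes from 0.016 to −0.033 and 0.0065. Shifts of that size are small beside the list mean, so these rescalings could hardly have removed it. The values show only that these 2 rescalings do not account for the list mean, again without resting on the spread between libraries. An effect of the genotype on these genes within roots may remain, as a hypothesis found and tested on the same data.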

How the results depend on the processing

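Values scaled to the summed fragments, voom, quantile normalization of the list tests, the 2-fold minimum in promoter tests, and genes measured in both tissues were chosen after seeing the data. Median-ratio scaling and no filter changed no call among 206 named gene effects; fits with no variance trend changed 2, both interactions of AHA genes. Counts stayed within 1.5 times except where given here, and where no cause is given the cause was not tested. With a 2-fold minimum, which by construction removes small changes, shoots had 957 genes (797 higher, 160 lower), roots 306 (94, 212), the interaction 1209 (230, 979) and WT tissues 8238 (4292, 3946). Scaled to the summed fragments, 3914 genes were lower in shoots, and the interaction was higher for 3145 and lower for 7697; AHA1 and AHA2 in shoots turned to 0.058 and 0.11. With quantile normalization they turned to 0.10 and 0.11, and vacuolar pumps to 0.023 in shoots and −0.014 in the interaction. Voom turned root hair markers in the interaction to −0.16. Interactions of single genes that turned were AHA1 (−0.13 with quantile normalization, −0.061 scaled to the summed fragments), AHA2 (−0.040 with quantile normalization), MRD1 (−0.25) and VHA-E3 (−0.17) scaled to the summed fragments, IRT1 (−0.68), JMJD5 (−0.99) and FLC (0.87) at a pseudocount of 0.1, EXPA10 (0.060) and CASP2 (0.16) at 5, and with voom PIF4 (0.19), COL2 (−0.26), FRO2 (−0.24), IRT1 (−1.47), JMJD5 (−1.23), FLC (1.104) and BRN1 (−0.16). The correlation of fold changes between tissues was 0.125 without a filter, 0.155 with a filter at FPKM 5, 0.0813 with quantile normalization, 0.115 scaled to the summed fragments and 0.121 with voom. Its covariance was 0.0399 and 0.00897 at pseudocounts of 0.1 and 5, 0.0149 without a filter, 0.0250 with the filter at FPKM 5, 0.0118 with quantile normalization, 0.0173 scaled to the summed fragments and 0.0536 with voom. Lists past the test with an estimated correlation were 8 in shoots and 11 in the interaction, and with fry, which tests a list without other genes, 26 in roots and 27 in the interaction. Replicate numbers did not pair the samples: deviations of libraries with the same number correlated at −0.044 to 0.042, and 4 of 12 libraries correlated best with their own number. The replicate block gave 11524 genes in shoots, 7463 in roots, 10521 in the interaction and 18266 between WT tissues, and changed no list call and 1 named gene call, the interaction of HY5, which it added. Leaving out each library gave 10766 to 11686 genes in shoots (5155 to 5585 higher, 5557 to 6101 lower), 6505 to 7585 in roots (3706 to 4381, 2793 to 3216), 9939 to 10213 in the interaction (5308 to 5475, 4603 to 4757) and 17858 to 18239 between WT tissues (9240 to 9501, 8541 to 8808). It gave a correlation of 0.129 to 0.134, a covariance of 0.0195 to 0.0201, and 2441 to 2672 genes called the same way and 1808 to 2005 called opposite ways. Calls of AHA7 in shoots and of CESA4 and PCNA1 in roots were lost without single libraries and under other settings, with values given beside them. Interaction calls were also lost for root hair markers and iron at a pseudocount of 0.1, iron and aquaporins with quantile normalization, iron with voom, and starch scaled to the summed fragments, and xyloglucan endotransglucosylases gained one with voom; in shoots vacuolar pumps lost theirs with voom (adjusted p = 0.0862). Promoters of 500 and 1500 bp kept each evening element result on its side of the threshold, but not CCA1-binding sites lower in roots (either length) or the shuffled sequence higher in shoots (500 bp). With the 2-fold minimum, the odds ratio of the evening element in genes lower in shoots turned from 0.998 to 2.41 (adjusted p = 0.00310), and 5 results of the other motifs no longer passed, at odds ratios of 1.24 to 1.45 in smaller sets. Low genes were recovered less often in simulated data: at a WT level under 5 FPKM, 23 of 47 genes in shoots and 36 of 60 in roots, and at 5 FPKM or more 134 of 153 and 117 of 140. The changes were planted on the FPKM scale and shrink in low genes on the log2(FPKM + 1) scale, which by construction lowers their recovery. The part that depth has in this was not tested.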

Other observations

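The tests of the 45 genes changed at least 2-fold the same way in both tissues were set before their results were seen, but the genes named here were chosen after their values were seen. Among these genes, further clock and light genes fell in CCA1-ox shoots and roots: TOC1 (log2 fold changes −1.14 and −1.21), BOA (−2.38 and −1.21), RVE8 (−1.15 and −1.07), RVE1 (−1.18 and −1.96), COR27 (−1.27 and −1.66), COL9 (−1.78 and −2.22) and HYH (−1.25 and −1.19). PRR9 (1.29 and 1.41), COL5 (1.62 and 1.25), BBX28 (1.203 and 1.74) and the flowering repressors FLC (1.27 and 1.12) and MAF5 (1.36 and 1.21) rose in both. The flavonoid genes F3H (−1.21 and −1.79) and FLS1 (−1.17 and −2.17) fell in both.

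A chromosome region that differs between the strains would place many of the 45 genes side by side, but no more than 2 lay within 500 kb, against 4 at the 95th percentile of 10000 random sets, which argues against a single region. Of the 45 genes, 16 (35.6%) held the evening element in the 1000 bp upstream, against 7.02% of the other tested genes (odds ratio 7.31, Fisher's exact test, two-sided, p = 3.34e-08, not adjusted). It was present in 5 of 16 genes higher in both and 11 of 29 lower in both. A candidate explanation is that CCA1 acts on part of these genes through this element, in both directions. Binding was not measured, and several of the 45 are clock genes long known to carry the element.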
